A study of Homo sapiens with 132 samples.

How the data were processed

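The series measured gene expression in a human embryonic kidney cell line by two-channel arrays, 132 arrays of 6652 probes. The deposited values are log ratios of the 2 channels, 1 value per probe and array, read as log2. The labels do not state the base, which channel is the numerator, the dye orientation or how the authors normalized the arrays. The values carry both signs, lie around 0 and have array medians from -0.0853 to 0.1492, from which a log ratio centred near 0 was read. Missing values made up 17.3% of the table and were left missing. An array is 1 sample, and nothing says which were separate cultures, so the tests measure the spread between these samples only.

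Groups were taken from the suffixes of the titles: p65 (55 arrays), krab (47), vp16 (3), k (2) and p (2). The 23 arrays without a suffix were put in no group and entered no comparison, and k and p arrays were kept apart except in 1 alternative. Probes were matched to genes by the identifiers of the platform annotation: 5305 had 1 gene symbol, 197 several and 1150 none. In total 6 probes for genes of the sex chromosomes that could show a person's sex were left out.

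Differences between groups were tested with limma 3.58.1 in R 4.3.3, with 1 linear model for p65, krab and vp16 arrays and empirical Bayes moderation, on probes with a value in at least 70% of p65 and of krab arrays. A probe passed at a Benjamini-Hochberg adjusted p under 0.05. The means against the reference channel also had to lie at least 0.5 from 0, except where members of gene lists were counted. Probes of 1 gene were averaged for the tests of 31 gene lists with limma's cameraPR at a preset correlation of 0.01, on lists with at least 5 measured genes, and again with an estimated correlation. Members of a list were also adjusted over the list alone. Shares of probes at an absolute log ratio of at least 1 were compared by permutation of the group labels, and lines of 1 code name by re-pairing, each with 100000 draws in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9.

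Genes named in the text followed a rule, apart from some that were picked out after their values were seen. For p65 against krab it took the 12 largest differences in each direction among passing probes of a single gene, and up to 4 members of a gene list that passed or had at least 3 called members. For the vp16 comparisons it took the 8 largest in each direction, for the reference comparisons the 10 largest, for the changed probes the 10 most frequent genes and for opposite calls the 10 largest, with at most 1 entry per gene. RELA, ZNF10 and VEGFA were always included where measured. Groups, comparisons, tests, gene lists, this rule and most alternatives were set before the data were examined.

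The limma tests were tested on simulated data with the same missing values: for p65 against krab, 92% of 50 probes with an added difference of 0.25 were recovered, and for vp16 against p65 12% at 0.25, 58% at 0.5 and 98% at 1, with 15 and 6 false calls. The simulated noise was independent between probes and equally wide on every array. In the data the SD of an array ran from 0.128 to 0.648, so these figures hold for such simulated noise only. The re-pairing test passed in 4 of 100 simulated runs without a shared effect and in 100 of 100 runs with one of 0.3. The alternatives covered centring, quantile normalization, the filter on missing values, averaging of probes, array weights, robust moderation, the k and p arrays, the code name as a block and the name families. For vp16 each array was left out in turn. Alternatives chosen after the data were seen were the sign turned in 5 arrays (the array of each opposed pair that was less like the other arrays), leaving out the 11 arrays of opposed pairs, leaving out arrays with over 40% of values missing, and reading the values as natural logarithms.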

Results

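Gene expression was measured with two-channel arrays in a human embryonic kidney cell line. The series title names artificial transcription factors, which are engineered DNA-binding proteins joined to a domain that acts on transcription. The table held 6652 probes on 132 arrays, and each value was the log ratio of the 2 channels of 1 array. Each array had its own title, made of a code name and in most cases a suffix, and is called a line here by that title. The suffixes were p65 in 55 lines, krab in 47, vp16 in 3, k in 2 and p in 2, and 23 lines had no suffix. The suffixes p65 and vp16 are names of transcriptional activation domains, from the NF-kB subunit RELA and from a herpesvirus protein, and krab is the name of a repression domain of zinc-finger proteins. Between 2967 and 6467 probes had a value on an array, with 3336 to 6411 in p65 lines, 2967 to 6399 in krab lines and 5407 to 5642 in vp16 lines. The number of arrays limits the precision of every value below.

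Neither the base of the logarithm nor the channel on top of the ratio was stated. Values are read as log2, natural logarithms cannot be excluded, and "positive" and "negative" describe the deposited ratio and not the direction of expression. RELA, whose product gives the p65 domain, did not settle the direction. Its log ratio was 0.12 ± 0.23 (SD, n = 55) in p65 lines and 0.19 ± 0.20 (SD, n = 47) in krab lines, a difference of -0.07 with limma and a Benjamini-Hochberg adjusted p of 0.362. ZNF10, a source of KRAB domains, was not measured. Some pairs of arrays ran against each other: 18 of 8646 pairs had a Pearson r over probes below -0.3. Of these, 9 were among p65, krab and vp16 lines. Such an r does not tell a turned sign from a difference between the lines. The sign of single arrays is not settled, and the main comparisons are also given with the sign turned in 5 arrays.

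The comparison of p65 with krab lines asks which genes differ between lines that carry an activation domain and lines that carry a repression domain. CRABP2, a carrier of retinoic acid, had a log ratio of 0.38 ± 1.21 (SD, n = 55) in p65 lines and of -0.44 ± 0.91 (SD, n = 47) in krab lines. COL6A1, a collagen VI chain, stood at 0.58 ± 1.02 (SD, n = 41) against -0.16 ± 0.41 (SD, n = 34), and PTPRN, a protein of secretory granules, at 0.71 ± 1.10 (SD, n = 45) against -0.02 ± 0.17 (SD, n = 38). ANXA1, a phospholipid-binding protein that restrains inflammation, went the other way, at -0.32 ± 1.01 (SD, n = 55) in p65 lines and 0.65 ± 0.65 (SD, n = 47) in krab lines. ADAMTS1, a secreted metalloprotease, was at -0.45 ± 0.55 (SD, n = 55) against 0.11 ± 0.43 (SD, n = 47). CGA, the shared alpha subunit of the glycoprotein hormones, was positive on average in both groups and lower in p65 lines, at 0.22 ± 0.55 (SD, n = 55) against 0.74 ± 0.82 (SD, n = 47).

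With limma, 298 of 4994 probes passed a Benjamini-Hochberg adjusted p of 0.05, 151 of them higher and 147 lower in p65 lines. Among the higher ones, CRABP2 differed by 0.83 (SE 0.207, adjusted p = 0.00929) and was positive in 39 of 55 p65 lines and negative in 24 of 47 krab lines. COL6A1 differed by 0.73 (adjusted p = 0.00789) and PTPRN by 0.73 (adjusted p = 0.00942). The other 9 of the 12 largest positive differences ran from 0.70 for FRY, a protein of cell shape and spindle control, to 0.47 for SLC6A3, the dopamine transporter. They included NFATC1, a calcium-regulated transcription factor, at 0.62 (adjusted p = 0.00372), CA11, a carbonic anhydrase relative, at 0.57 (adjusted p = 0.00161), and SOX9, a transcription factor of cartilage and testis development, at 0.53 (adjusted p = 0.00703). CRIP2 (0.67), PTMS (0.65), FKBP8 (0.59) and SEZ6L2 (0.49) made up the rest. Among the lower ones, ANXA1 differed by -0.97 (SE 0.165, adjusted p = 0.000115) and was negative in 6 of 47 krab lines and positive in 17 of 55 p65 lines. ADAMTS1 differed by -0.56 (adjusted p = 0.000115), ID4, an inhibitor of basic helix-loop-helix factors, by -0.58 (adjusted p = 0.0010) and PMAIP1, the pro-apoptotic protein NOXA, by -0.52 (adjusted p = 0.000386). CGA differed by -0.52 (adjusted p = 0.011), and PCDH9, CITED2, H4C3, IDI1, SELENOP, HMGCS1 and BTG1 by between -0.44 and -0.32. IDI1 and HMGCS1 are enzymes of cholesterol synthesis.

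**Figure D1:**
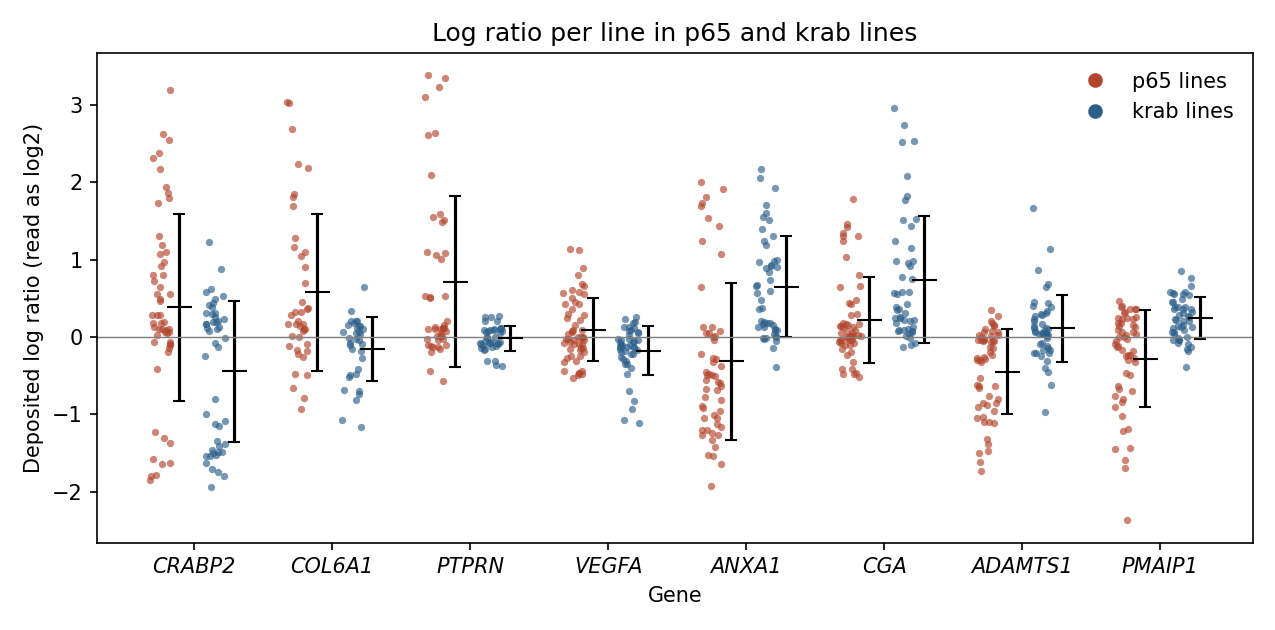
Deposited log ratio (vertical axis, read as log2) of 8 genes in each p65 and each krab line; points are lines and bars are the mean ± SD. PTPRN reached a log ratio of at least 1 in 15 of 45 p65 lines and in 0 of 38 krab lines, while CGA was above 0 on average in both groups.

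Large values of these genes, counted here with the deposited signs, lay in a part of the lines. PTPRN was at or above 1 in 15 of 45 p65 lines and in 0 of 38 krab lines, and COL6A1 in 12 of 41 p65 lines and 0 of 34 krab lines. The 15 include 05-E09_p65, with PTPRN at 3.10, which is among the 5 arrays turned in the alternative. CRABP2 was at or above 1 in 14 p65 lines and 1 krab line, and at or below -1 in 9 p65 lines and 18 krab lines. ANXA1 was at or below -1 in 16 p65 lines and in 0 krab lines, and at or above 1 in 9 p65 lines and 11 krab lines. VEGFA, a growth factor of blood vessels, differed by 0.27 (SE 0.0743, adjusted p = 0.0165 with limma), from 0.10 ± 0.41 (SD, n = 55) in p65 lines to -0.18 ± 0.32 (SD, n = 45) in krab lines. It was negative in 33 of 45 krab lines and positive in 26 of 55 p65 lines.

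Of the 31 gene lists fixed before the data were examined, 3 passed an adjusted p of 0.05 in the camera test for p65 against krab lines, and 0 did with an estimated correlation between genes. Genes of the G2 and M phases of the cell cycle were lower in p65 lines, with a mean difference of -0.087 over 26 genes (camera adjusted p = 9.21e-07; adjusted p = 0.314 with an estimated correlation). Of these genes 4 were lower and 0 higher with limma over all genes, and 11 were lower adjusted over the list alone. The 4 were UBE2C (-0.17, adjusted p = 0.0263), CENPA, a centromere histone (-0.17, adjusted p = 0.0164), CDK1, the kinase that drives entry into mitosis (-0.16, adjusted p = 0.0399), and PTTG1 (-0.13), which was picked out after its values were seen. HMMR, which the rule also took, was at -0.14 and did not pass with limma (adjusted p = 0.112). Histones were lower too, with a mean difference of -0.103 over 14 genes (camera adjusted p = 0.00115; adjusted p = 0.514 with an estimated correlation). The 3 called members were H4C3 (-0.36), H2AZ1 (-0.30, adjusted p = 0.000513) and H2AZ2 (-0.18, adjusted p = 0.00599), and 5 were lower adjusted over the list alone. H2AX, which the rule also took, was at -0.17 and did not pass with limma over all genes (adjusted p = 0.0847).

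Targets of p53 were higher in p65 lines, with a mean difference of 0.0815 over 13 genes (camera adjusted p = 0.0417; adjusted p = 0.824 with an estimated correlation). The 4 higher members were GADD45B, a stress-induced gene of growth arrest (0.31, adjusted p = 0.0351), BAX, a pro-apoptotic pore protein (0.29, adjusted p = 0.0103), CDKN1A, an inhibitor of cyclin-dependent kinases (0.26, adjusted p = 0.0369), and PHLDA3 (0.26), named after its values were seen. The list's 1 lower member was PMAIP1, and 6 members passed adjusted over the list alone, 5 higher and 1 lower. The call of this list was lost with array medians subtracted (adjusted p = 0.0764) and with the sign turned in 5 arrays (adjusted p = 0.0531). Immediate early genes, which respond first to growth signals, did not pass as a list (camera adjusted p = 0.613). Of the 13 measured, 4 were higher in p65 lines and 1, CCN1 (-0.17), was lower, and 5 passed adjusted over the list alone. JUNB was at 0.43 (adjusted p = 0.0141), IER2 at 0.25 (adjusted p = 0.03), KLF10 at 0.19 (adjusted p = 0.0135) and NR4A1 at 0.16. MYC, which the rule also took, was at 0.18 and did not pass with limma (adjusted p = 0.454). NR4A1 and CCN1 were picked out after their values were seen. For the 14 measured targets of NF-kB, the factor that p65 belongs to, the mean difference was 0.0018 (camera adjusted p = 0.858). With limma 0 of them passed over all genes, and 0 adjusted over the list alone. The 28 lists that did not pass had camera adjusted p values from 0.613 to 0.928.

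The number of calls changed with the arrays used, their signs and their weights. With the sign turned in 5 arrays 40 probes passed, 10 higher and 30 lower in p65 lines, of which 39 were among the 298, and without the 11 lines that belonged to opposed pairs 171 passed, 82 higher and 89 lower, of which 154 were among them. With array weights 15 passed, 1 higher and 14 lower, and with the code name as a fixed block 21 passed, 4 higher and 17 lower. In the fixed block only names with both suffixes inform the difference. With the code name as a random block 335 passed, including all 298, at a correlation of 0.0461 between lines of 1 name. Quantile normalization gave 84 higher and 134 lower. Of the 36 called genes named for p65 against krab, 33 lost the call with array weights, 31 with the fixed block, 28 with the sign turned and 5 under quantile normalization. ANXA1 kept its call with the sign turned, without the 11 lines, with array weights and with the fixed block, while CRABP2 lost it with the sign turned (0.53, adjusted p = 0.205), with array weights (0.38, adjusted p = 0.353), with the fixed block (1.00, adjusted p = 0.0908) and under quantile normalization (0.50, adjusted p = 0.0509). VEGFA lost it in the 4 alternatives in which ANXA1 is named as keeping it, at 0.21 with the sign turned (adjusted p = 0.148). Code names fell into a family that starts with F and a family that starts with a number. In F names alone 83 probes passed. In number-led names alone 0 of 3881 passed with limma and 333 were at an unadjusted p under 0.05, with differences of 1.53 for CRABP2 and -1.47 for ANXA1. A test of the difference between the families passed for 0 of 4991 probes with limma, and 254 were at an unadjusted p under 0.05.

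The comparisons with vp16 lines ask whether another activation domain gives other log ratios than p65 and krab. WIF1, a secreted inhibitor of Wnt signals, was higher in vp16 lines, at 0.69 ± 1.01 (SD, n = 3) against -0.09 ± 0.24 (SD, n = 51) in p65 lines. POU3F2, a transcription factor of neural cells, was higher in vp16 than in krab lines, at 0.92 ± 1.22 (SD, n = 3) against -0.33 ± 0.29 (SD, n = 39). VEGFA was at 0.96 in F475_vp16, at 0.26 in F547_vp16 and at -0.15 in F109_vp16, and its vp16 minus krab difference of 0.54 did not pass with limma (adjusted p = 0.691). With limma, 1 probe of 4993 passed for vp16 against p65, that of WIF1 (difference 0.79, SE 0.156, Benjamini-Hochberg adjusted p = 0.0095), and 180 were at an unadjusted p under 0.05. For vp16 against krab, 1 probe passed, that of POU3F2 (difference 1.26, SE 0.248, adjusted p = 0.011), and 282 were at an unadjusted p under 0.05. Both calls rested on F109_vp16: without it the differences were 0.21 for WIF1 (adjusted p = 1.00) and 0.62 for POU3F2 (adjusted p = 0.999), and the counts were 0 and 2. WIF1 also lost its call under quantile normalization (0.61, adjusted p = 0.0881).

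The comparison of each group with the reference channel asks which log ratios departed from 0 on average. Counts of positive and negative lines here are with the deposited signs, and turning the sign of a line changes them. In p65 lines GRN, a secreted growth factor of lysosomes, was positive in 55 of 55 lines at 0.51 ± 0.37 (SD, n = 55), and BLVRB, an enzyme of heme breakdown, in 53 of 55 lines at 0.56 ± 0.42 (SD, n = 55). MGAT3, an enzyme that branches N-glycans, was positive in 0 of 41 p65 lines at -0.64 ± 0.28 (SD, n = 41). In krab lines CGA was at 0.74 ± 0.82 (SD, n = 47) and CAPNS1, a calpain subunit, at 0.54 ± 0.36 (SD, n = 47). TSPAN4, a membrane protein of the tetraspanin family, was negative in 41 of 41 krab lines at -0.57 ± 0.22 (SD, n = 41).

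With limma, 15 of 4994 probes in p65 lines had a mean of at least 0.5 from 0 and an adjusted p under 0.05, 7 positive and 8 negative. They included PTPRN (0.71, adjusted p = 5.96e-07), COL6A1 (0.58, adjusted p = 2.48e-05), FKBP8 (0.57, adjusted p = 8.41e-08), GRN (adjusted p = 3.61e-21) and BLVRB (adjusted p = 1.29e-17). On the negative side were MGAT3 (adjusted p = 6.52e-20), PDCD4, a repressor of translation (-0.62), PTPN11, a tyrosine phosphatase (-0.55), EEA1, a tether of early endosomes (-0.51), and CASP8AP2 (-0.50). In krab lines 14 probes passed, 5 positive and 9 negative. CGA (adjusted p = 2.59e-10), ANXA1 (0.65, adjusted p = 2.5e-06), CCNA1, a cyclin of the germ line (0.55, adjusted p = 9.18e-07), and CAPNS1 (adjusted p = 1.87e-17) were positive. PDCD4 (-0.70), MGAT3 (-0.68), PTPN11 (-0.67), SMG1, a kinase of RNA surveillance (-0.58), TSPAN4 (adjusted p = 7.73e-21) and EEA1 (-0.53) were negative. The signs among the calls followed the scaling: under quantile normalization 1 of 12 calls was positive in p65 lines and 22 of 37 in krab lines. With the sign turned in 5 arrays the counts were 8 in p65 lines, 1 of them positive, and 13 in krab lines.

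Genes of the ribosome and of oxidative phosphorylation lay above 0 on average in both groups. List members were counted here at an adjusted p under 0.05 alone, without the limit of 0.5. Small departures from 0 were common. With probes averaged, 2669 of 3931 genes in p65 lines had an unadjusted p under 0.05 with limma, of either sign. In krab lines 2387 of 3931 did. All 31 measured ribosomal protein genes were positive with limma in p65 lines, with a mean of 0.266 (camera adjusted p = 4.11e-11; adjusted p = 0.540 with an estimated correlation), and 28 of 31 in krab lines, with a mean of 0.260 (camera adjusted p = 2.66e-11; adjusted p = 0.246 with an estimated correlation). With array medians subtracted these counts were 29 and 27. Of 42 genes of oxidative phosphorylation, 35 were positive and 2 negative in p65 lines (mean 0.190, camera adjusted p = 3.97e-08; adjusted p = 0.540 with an estimated correlation). In krab lines 38 were positive and 1 negative (mean 0.209, camera adjusted p = 5.36e-11; adjusted p = 0.221 with an estimated correlation). Of 26 proteasome genes, 19 were positive and 2 negative in p65 lines (mean 0.152, camera adjusted p = 0.00212; adjusted p = 0.540 with an estimated correlation). In krab lines 17 were positive and 3 negative (mean 0.138, camera adjusted p = 0.00305; adjusted p = 0.369 with an estimated correlation). Histones passed in krab lines, with 12 of 14 positive and a mean of 0.205 (camera adjusted p = 0.00295; adjusted p = 0.318 with an estimated correlation). The reference channel's own spread and any dye effect are not part of these tests.

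The share of probes with an absolute log ratio of at least 1 measures how far a line lay from the reference, and the positive share of these probes shows to which side. The genes that passed this level most often over p65 and krab lines were CRABP2 in 42 lines, ANXA1 in 36, PTMS, a prothymosin relative, in 30, and CLIC1, a chloride channel protein, in 29. TSC22D3, a glucocorticoid-induced gene, did so in 27 lines. With the deposited signs TSC22D3 was negative in 12 of 13 p65 lines and 14 of 14 krab lines. In the alternative with turned signs it was positive in the p65 line of F480, so these shares hold for the deposited signs only. ASS1 followed in 22 lines, ENO2 and CGA in 20 each, TNFRSF14 in 18 and PRAME in 17. These counts also depend on missing values: TNFRSF14 was measured in 22 p65 and 30 krab lines, and CRABP2 in 55 and 47. Of 6646 probes, 2159 (32.5%) passed the level in at least 1 of these lines, 1020 in 1 line only and 55 in at least 10.

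The percent of changed probes was 1.30% ± 1.89 (SD, n = 55) in p65 lines and 0.805% ± 1.30 (SD, n = 47) in krab lines, and the difference of 0.491 was within the spread between lines (two-sided permutation p = 0.134). It was 0.441 in F names (permutation p = 0.279) and 0.578 in number-led names (permutation p = 0.338). A level of 3-fold gave a difference of 0.176 that passed (permutation p = 0.029), and so did the 33 names with both suffixes, at 0.676 and higher in the p65 line of 26 names (permutation p = 0.0365). The farthest line was F081_p65 with 10.4% of its probes changed, 391 above and 129 below, among them SLC6A3 at 3.54 and RAC2, a small GTPase of blood cells, at 3.38. The positive share was 62.5% ± 35.3 (SD, n = 45) in p65 lines and 25.1% ± 23.8 (SD, n = 27) in krab lines with at least 10 changed probes. The difference of 37.4 points had a two-sided permutation p of 2e-05, the smallest these permutations can give. It was 34.6 in F names (permutation p = 0.00104), 43.6 in number-led names (permutation p = 0.00284) and 33.6 with the sign turned in 5 arrays (permutation p = 6e-05). It was smaller at a level of 1.5-fold, 18.6 points, and with values read as natural logarithms, 23.9 points (permutation p = 0.0001 for each). Quantile normalization gives every array the same distribution and left a difference of -0.287 (permutation p = 0.14).

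**Figure D2:**
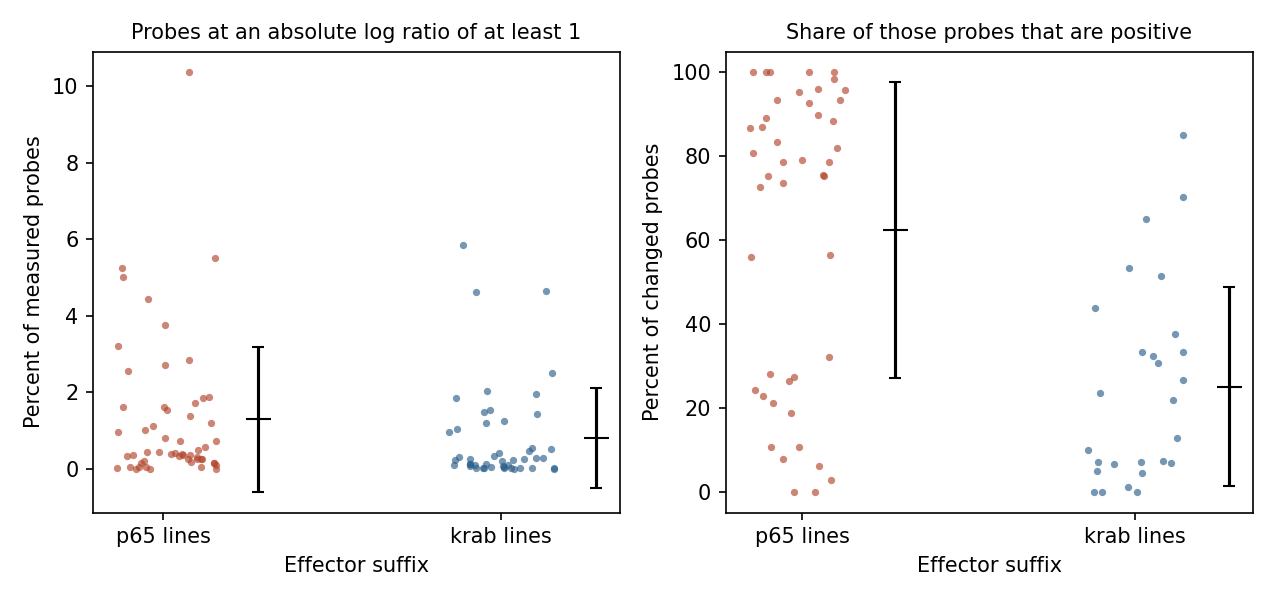
Percent of measured probes at an absolute log ratio of at least 1 (left) and percent of those probes that are positive (right) in p65 and krab lines; points are lines and bars are the mean ± SD. The positive share averaged 62.5% in p65 lines and 25.1% in krab lines, with a wide spread in both.

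A total of 33 code names had both a p65 and a krab line, which asks whether lines of 1 name respond alike or in opposite ways when the domain differs. CRABP2 was at an absolute log ratio of at least 1 with opposite signs in the lines of 8 names, positive in the p65 line of all 8; with the sign turned in 5 arrays it was opposite in 5 names. ANXA1 was opposite in 5 names and negative in the p65 line of all 5, also with the sign turned. PTMS was opposite in 5 names and positive in the p65 line of all 5, and opposite in 4 with the sign turned. In the 08-A04 lines CRABP2 was at 2.38 with p65 and -1.80 with krab, and PCDH9, a cell adhesion protein, at -2.07 and 1.594. In the F121 lines PTPRF, a receptor tyrosine phosphatase, was at 1.98 with p65 and -2.25 with krab, and CA2, a carbonic anhydrase, at -1.92 and 1.57. VEGFA in the F121 lines was at 0.68 with p65 and -1.12 with krab.

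Over all 33 names, 83 opposite probe calls were positive in the p65 line and 18 were positive in the krab line, or 59 and 20 with the sign turned in 5 arrays. For the sum of the 83 and 18, random re-pairing of the krab lines gave a mean of 32.7 (95% range 14 to 62; two-sided permutation p = 3e-05), and re-pairing within name families gave a permutation p of 1e-05, the smallest these permutations can give. Calls of the same sign numbered 43 against 50.2 for re-paired lines (permutation p = 0.695). With the sign turned in 5 arrays 79 calls were opposite against 27 (permutation p = 6e-05). The 3 names 08-A04, F121 and F480 held 28, 24 and 17 of the calls with the deposited signs, and 16 names had any. The p65 array of F480 was among the 5 turned, which left F480 with 2 opposite calls and 08-A04 and F121 with 28 and 24, and the 9 calls of 05-E09 were then all of the same sign. Further large opposite values were ANXA1 in 08-A04 (-1.53 with p65 and 2.05 with krab), CACNB3, a calcium channel subunit, in F121 (2.49 and -1.07), and CKB, the brain creatine kinase, in 08-A04 (1.49 and -1.996). TMSB4X (-1.04 and 2.35) and CHD4 (1.96 and -1.35) in F121 and PFKP (2.16 and -1.16) in 08-A04 completed the 10 largest with a single entry per annotated gene. Under quantile normalization, which gives every array the same positive share, 25 calls were opposite (permutation p = 0.00277), and their balance of 7 positive in the p65 line is therefore not comparable.

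**Figure D3:**
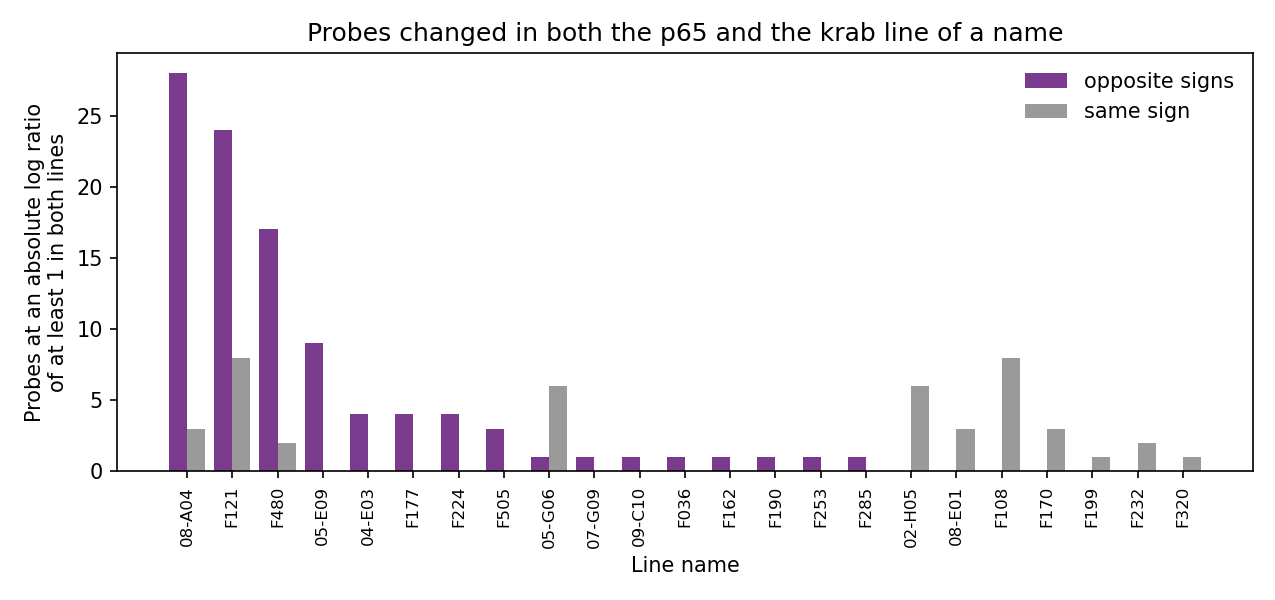
Number of probes (vertical axis) at an absolute log ratio of at least 1 in both the p65 and the krab line of a code name (horizontal axis, names with any such probe), with bars for opposite signs and for the same sign. With the deposited signs, the names 08-A04, F121 and F480 held 28, 24 and 17 opposite calls.

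As whole profiles, the closeness of the p65 and krab lines of 1 name depended on the measure. The mean Pearson r over probes was 0.252 in the 33 names against 0.211 for re-paired lines (95% range 0.162 to 0.264; two-sided permutation p = 0.114). Re-pairing within name families gave a permutation p of 0.380. By rank the mean was 0.290 against 0.229 and passed (permutation p = 0.0117), and with the k and p lines counted as krab and p65 it was 0.284 against 0.226 (permutation p = 0.0253). It did not pass over probes with a value in every array (0.224 against 0.203; permutation p = 0.432), over the 1000 probes with the largest SD, where it differed from re-paired lines by -0.00503 (permutation p = 0.875), with group means subtracted (permutation p = 0.118) or with the sign turned (permutation p = 0.185). With the deposited signs names ranged from -0.307 in F480 to 0.851 in F232, and probes are not independent replicates within such an r.

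The labels also hold 5 pairs of lines with the same suffix whose names differ by an added letter or number, the meaning of which is not stated. Their mean Pearson r over probes was 0.499 against 0.275 for random unrelated pairs of the same suffixes (95% range 0.0987 to 0.462; two-sided permutation p = 0.0163). The values were 0.420 for F101 and F101m03, 0.667 for F102m01 and F102m15, 0.587 for F103 and F103m11, 0.655 for F231 and F231p, and 0.164 for F121 and F121m. Some lines of unrelated names were closer. F101_krab and F231p_krab had an r of 0.914, the highest of all array pairs, and F101_krab and F103_krab one of 0.888. A baseline over all unrelated pairs does not separate a related name from such likeness. VEGFA was at 0.68 in F121_p65 and at 0.16 in F121m_p65. With the group means subtracted from each probe the mean was 0.164 against -0.0164 for random pairs, which did not pass (permutation p = 0.0763).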

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

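The tests of a few lines with large values, of name family, of turned signs, of a domain difference common to all names, of larger responses, of 3 names alone and of the domain effect on ribosomal genes were chosen only after the result was seen. For turned signs, for 3 names alone and for larger responses, the bound that would exclude the explanation was also made stricter after the result, and the first bounds would have excluded all 3.

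Several results came from samples that no comparison used, and the labels name no control samples to set them against. The line 11-48-02, which had no suffix, had 1.86% of its probes at an absolute log ratio of at least 1, the most among the 23 lines without a suffix. In the same line SOX9 was at 2.50, the highest value of a named gene in these lines. The line M43 held their lowest, GUCA1A, a regulator of photoreceptor signals, at -4.01. Among the k and p lines, F322_p had the most changed probes, 0.526%.

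The first pattern is the 298 probes that differed between p65 and krab lines, with CRABP2 and ANXA1 in front. Chance is an unlikely source of the count: 1 of 100 splits of the lines, the real one, gave as many, and the highest other gave 0. A share below 1 of 100 could not come from this number of splits, and they moved lines freely across code names. Name family was argued against as the cause by its similar spread over the suffixes: 16 of 55 p65 and 12 of 47 krab lines had number-led names. The count with the family in the model was 0.977 of the count without it, and at this spread it could move little. Other batches were not tested. A few lines with large values may carry part of the count, since a rank test over lines called 167 probes, 147 of them among the 298, and array weights left 15. Turned signs of single arrays stayed open: 40 probes passed with the sign turned in 5 arrays, which can follow from right or wrong signs. Those 5 arrays had a positive r with the mean of the other arrays (0.0936 to 0.232). This argues against a turned sign in them unless a dye effect common to all arrays gave that r. F320_krab, at -0.137, and 08-A04_krab, at 0.0504, had a lower r but were not turned. The alternative therefore does not test the sign of 08-A04_krab, whose name held the most opposite calls.

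The second pattern is the opposite calls in the p65 and krab lines of 1 name, 83 positive with p65 and 18 with krab (59 and 20 with the sign turned in 5 arrays), such as CRABP2 and PCDH9 in 08-A04. A domain difference common to all names and of the same size in each falls short of it, since the sum lay above the 95% range of re-paired lines, which ended at 62, as did the 79 calls with turned signs above 51. Leaving out any 1 name kept the permutation p at or below 0.00126, or 0.00167 with turned signs. Re-pairing also breaks a response size shared by the lines of a name, so it cannot exclude a common difference that is larger in some names. Larger responses alone stayed open. With the deposited signs, which are not settled, 70.1% of shared calls were opposite, above a re-paired 95% range that ended at 65.4%. With turned signs the share of 54.9% lay within a range that ended at 57.1%, but this share cannot decide the question. F480_p65 was turned for its r of -0.307 with F480_krab, the other line of its name. Turning it changed F480 from 17 opposite and 2 same-sign calls to 2 and 17. Whether 08-A04, F121 and F480 alone carry the pattern, and what explains the calls of the 30 other names, stayed open too, since these 3 were picked for their calls and leaving them out lowers the count and the share by that choice (to 32 calls, permutation p = 0.047, and 51.6%). An axis shared by all lines was not decided: removing the first principal component left 17 calls against 7.33 (permutation p = 0.063), but that component itself separated p65 from krab lines (permutation p = 8e-05), so its removal takes away the outcome, and a response specific to each name, the biological explanation the design gives, stays open as well.

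The third pattern is the positive log ratio of ribosomal protein genes in most lines. The domain as its cause was argued against by a p65 minus krab difference of 0.0104 in the list median per line. The common reference or a dye effect may be its source, since lines without a suffix had a median of 0.219 and 125 of 132 lines (94.7%) were above 0, although the 3 vp16 lines had a median of 0.0082. A response to any zinc-finger protein stayed open, as untested.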

How the results depend on the processing

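Turning signs in 5 arrays and leaving out the 11 opposed arrays were chosen after seeing the data; in each case below where a count moved and no reason is given, the cause was not tested. For p65 against krab (298), 122 probes passed among the 2417 with a value in every array, 15 with array weights, 21 with the code name as a block (informed only by names with both suffixes), 83 in F names, 0 in number-led names (fewer arrays and probes), 40 with signs turned and 171 without the 11 arrays. The other 9 alternatives lay between 218 and 335. For vp16 against p65 (1) the counts were 4 with medians subtracted, 3 under quantile normalization, 3 with values in at least 3 arrays, 0 with values in every array (fewer probes), 2 with probes averaged, 22 with array weights, 2 with robust moderation, 4 with the block and 2 with signs turned. Leaving out 1 vp16 array gave 0 to 6. For vp16 against krab (1) they were 3 with medians subtracted, 34 under quantile normalization, 2 with values in at least 3 arrays, 0 with values in every array, 5 with probes averaged, 51 with array weights, 5 with k and p merged and 4 with the block. Leaving out 1 vp16 array gave 2 to 9. Counts of 0 are from limma, with 4.26% (against p65) and 6.04% (against krab) of 2417 probes at an unadjusted p under 0.05 for vp16 with values in every array, 131 probes without F109_vp16 and 333 in number-led names. For p65 against the reference (15) they were 1 with values in every array, 8 with probes averaged, 6 with array weights and 8 with signs turned. For krab against the reference (14) they were 25 with medians subtracted, 37 under quantile normalization, 3 with values in every array and 9 with array weights. With an estimated correlation 0 of the 3 gene lists passed camera.

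The percent of changed probes differed by 0.176 at 3-fold and by 0.676 within names, both now past the threshold. Under quantile normalization the positive share differed by -0.287, a value that says nothing, since this step fixes the share of every array. The same-name correlation passed by rank (0.290) and with k and p merged (0.284) but in none of the other 5 alternatives, and over the 1000 probes with the largest SD it differed from re-paired lines by -0.00503. At 3-fold 4 calls were opposite and did not pass, and the related-name correlation with group means subtracted was 0.164 against -0.0164 for random pairs and did not pass. Of the alternative values of the 36 called named genes of p65 against krab, 392 kept the call, 154 lost it and 0 turned in direction. Of those of the 4 genes not called, 60 stayed so and 1 gained a call, and turns in direction were not counted for these genes. For the p65 reference 74 kept and 28 lost the call, for the krab reference 89 and 6, for vp16 against krab 11 and 1, and for vp16 against p65 10 and 2. The code name was a block only as an alternative, since the labels state no pairing. The number of arrays limits all of this, and signal over background was not in the table.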

Other observations

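The test of a response size shared by the lines of a name was chosen only after the result was seen, as were the names left out of it and the turned signs; the splits of the lines and the test of difference profiles were planned.

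The 23 lines without a suffix, 19 of them with names that start with M, had a percent of changed probes from 0 to 1.86% with a median of 0.0773%, against medians of 0.437% in p65 lines and 0.247% in krab lines. The lines 11-48-02, M43, 08-02 and F121 lay above the p65 median, and the difference was not tested. The line M12 had MEIS3P1 at 2.18 and CRKL, an adaptor of kinase signals, at 1.67. In M38, NUPR1, a stress-induced chromatin protein, was at 1.82, and in M13 it was at 1.54. CCN3, a matricellular growth regulator, was at 1.82 in M33 and at 1.60 in M31, and at -1.19 in M38. PTPN11 was at -1.81 in 08-02, -1.78 in 11-48-02, -1.54 in M07 and -1.45 in M42. These genes were picked out after their values were seen.

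The line F121 without a suffix had 0 probes above 1 and 31 below -1, with MAP3K1, a kinase of stress signals, at -2.25 and VEGFA at -0.08. Over probes, which are not independent replicates, its r was 0.196 with F121_p65, 0.0771 with F121_krab and 0.476 with F121m_p65. In the k and p lines CRABP2 was at 0.47 in F322_k, 0.48 in F322_p, 0.19 in F324_k and -0.04 in F324_p. F109 had lines with all 3 domains: r was 0.0836 between p65 and krab, 0.0749 between p65 and vp16 and 0.158 between krab and vp16. The line M32 was part of 9 of the 18 pairs of arrays with an r below -0.3.

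For the vp16 comparisons, chance could not be excluded: 72 of 100 splits gave at least the 1 probe called against p65 (highest other 271), and 34 of 100 at least the 1 called against krab (highest other 1261). The median of the other splits was 5 against p65 and 0 against krab. Why some splits called many times the real count was not tested.

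Differences between p65 and krab lines of a name may be shared between names. The mean correlation of the 33 difference profiles was 0.0260 over 2660 probes, above 0.0223, the upper end of the 95% range of sign flips (one-sided permutation p = 0.0157), and 22 names had a positive mean with the others. The bound set beforehand took the deposited signs as right; with the sign turned in 5 arrays the mean was 0.0106 (permutation p = 0.109), so whether the differences are shared stays open. With the deposited signs r between 08-A04, F121 and F480, picked out for their opposite calls, was 0.524 for 08-A04 with F121, 0.445 for 08-A04 with F480 and 0.422 for F121 with F480.

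Names may also share the size of the response under both domains. The percent of changed probes in the p65 and krab lines of the 33 names had a Spearman rho of 0.353 (permutation p = 0.0433) and a Pearson r of 0.354 (permutation p = 0.0364). A Benjamini-Hochberg adjustment over these 2 p values leaves the larger as it is, so it adds no check. Without 09-C10 and F121, the 2 names with the most changed probes in the p65 line, rho was 0.2998 (permutation p = 0.0999) and r 0.265 (permutation p = 0.125). Without F170 and F121, the 2 with the most in the krab line, rho was 0.324 (permutation p = 0.0745) and r 0.399 (permutation p = 0.032), so rho passed in neither case. Within F names rho was 0.188 (permutation p = 0.388) and within number-led names 0.564 (permutation p = 0.0968), and it stays open.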
